A study of Mus musculus with 24 samples.

How the data were processed

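Expression was measured in mouse bone marrow-derived macrophages on 24 Affymetrix whole-genome mouse arrays, 3 for each of 8 groups formed by 4 media and the presence or absence of LPS. The values analysed are those the authors deposited, 1 log2 expression value per probe set and array. The submitters' processing notes name GCRMA and Partek without further settings. Samples were labelled with biotin and hybridised singly on each array. The labels do not state the log base, and log2 was inferred from the values, which run from 1.48 to 14.84 as 16-bit scanner intensities do on that scale. Array medians lay between 5.04 and 5.13, and no pair of arrays was identical. The raw image files were not used here. For arrays the number of replicates limits the precision, and here it was 3 per group.

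Probe sets were paired with genes through the platform table. Of 45101 probe sets 64 were controls, 932 named several genes, 9160 named none and 34945 named 1 gene, in all 18193 symbols. By Entrez number 34741 of these were found in the current gene table, which changed 0 symbols, and 204 were not found. A probe set was kept if its log2 value exceeded the median of all values (5.08) on at least 3 of the 24 arrays, whatever their group. This kept 25525 probe sets, 21939 of them with 1 gene. Where a gene had several kept probe sets (5768 genes), the one with the highest mean over all arrays stood for it, which left 11785 genes. Among 401 named genes 45 rest on a probe set whose name ending marks possible cross-hybridisation, and 65 on one that matches several transcripts of the same gene by its ending. Of 1763 results of other probe sets of named genes, 1154 were called in the same direction, 0 in the opposite one, and 609 had no call. The lowest group mean of 96 named genes lay below the filter, so their folds depend on background. Platform positions on the genome were not used here.

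A linear model with 1 mean per group was fitted to all 24 arrays in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation (trend and robust; median prior degrees of freedom 6.37). The 26 comparisons were LPS against none in each of the 4 media and averaged, each serum and the average of the 3 sera against no serum with and without LPS, the sera against each other with and without LPS, and the differences between media in the LPS response. Tests are two-sided, and p was adjusted by Benjamini and Hochberg within each comparison with a threshold of 0.05. Differences carry limma's standard error, and levels carry the SD of 3 arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

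Replicates G, H and I are separate replicate experiments per the labels, which do not say that each used separate animals. The p-values therefore measure the spread between experiments, and reach other animals only if the experiments used them. Whether the letters pair the arrays was checked on deviations from the group means. Over 84 pairs of arrays with the same letter from different groups the correlation across genes had a median of 0.062 (-0.046 to 0.183), and 17 pairs exceeded 0.1, whereas pairs with different letters had a median of -0.035. The experiment is not a term of the model and enters as a block in an alternative. The labels also give 3 array batches. They follow the experiments except for 1 array, the calf serum control of experiment H, to which they give the batch of experiment G. Whether that entry is right is not known here.

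The choices above, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. Of 36 gene lists, all written from general knowledge, each was tested with camera (correlation between genes preset at 0.01), adjusted over the lists within a comparison. They cover inflammatory cytokines, chemokines, interferon response, negative feedback on Tlr4, LPS effector enzymes and acute phase, LPS recognition and Toll-like receptor signalling, antigen presentation, cholesterol biosynthesis, LXR targets, PPAR and lipid storage, fatty acid synthesis, NRF2 and haem, glucocorticoid, amino acid and integrated stress, unfolded protein, immediate early, SRF, TGF-beta, retinoic acid and aryl hydrocarbon receptor responses, glycolysis and hypoxia, cell cycle, alternative activation, macrophage identity, complement and Fc receptors, lysosome and autophagy, apoptosis and survival, metals, growth factors and receptors, and markers of 7 other cell types. Of 268 list calls 162 held with a correlation estimated from the data, and the report gives the p of a list named there that did not. Members of a list were also adjusted over the list alone. Among these calls the median, mean and test differed in sign in 1.

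A gene could be named in a comparison if its adjusted p was under 0.05 and its difference had the same sign in experiments G, H and I. The largest changes were named, 8 higher and 8 lower for the 3 averaged comparisons, 5 and 5 for single sera against no serum and for mouse against human serum, and 3 and 3 for the others, leaving out uninformative names. Up to 4 such members of each list that passed, or that had at least 3 members past the threshold, could be named too. A set of 8 genes was always given for LPS comparisons, and one of 7 for serum comparisons, of which 5 had a named probe set past the filter. The remaining ones are not reported here.

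The procedure was tested on simulated data in the comparison of mouse serum with no serum without LPS. The noise had each gene's residual SD on these arrays, but was drawn independently for each gene and array. It recovered 18 of 67 genes raised or lowered by 0.5 (log2), 55 of 67 at 1 and 64 of 66 at 2. Of 154 calls 10 (6.49%) were unchanged genes. With no gene changed in the comparison of human with calf serum with LPS there were 0 calls. Camera called a list of 25 raised genes and did not call a list of 25 flat ones. Correlation between genes and effects shared within an experiment were absent, so false calls that arise from these were not tested.

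The alternatives were the experiment as a block, as a random block (duplicateCorrelation) and the array batch as a block, only the compared groups in the fit, no trend or robust moderation, array weights, no filter or a filter at the 75th percentile (7.84), the mean of a gene's probe sets or each probe set, arrays centred on their medians or quantile normalised again, at least a 2-fold change, an adjusted p under 0.01, and leaving out each array and each experiment. For lists they were an estimated correlation, fry and the block. Fry asks whether a list's genes move on balance one way, or in its mixed form whether they change in either direction, without comparing them with other genes.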

Results

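Gene expression was measured on 24 Affymetrix whole-genome mouse arrays, each hybridised with labelled cDNA from mouse bone marrow-derived macrophages (C57BL/6), which are macrophages grown from marrow cells. The cells were kept in medium with no serum, or with 5% fetal calf, mouse or human serum heated at 56 °C for 30 min. They were left unstimulated or given 25 ng/ml lipopolysaccharide (LPS, the bacterial ligand of the Toll-like receptor Tlr4) and harvested at 4 h. The 8 groups held 3 arrays each, from replicate experiments G, H and I. Array medians lay between 5.04 and 5.13 on the log2 scale, and replicates of a group correlated at Pearson's r of 0.983 to 0.992 across genes, which are not independent replicates. The first principal component (74.6% of the variance) parted arrays with LPS from those without. After the filter 11785 genes were tested. Changes are log2 differences ± standard error (SE) from limma with n = 3 arrays per group, adjusted p is over all genes, and levels are log2 means ± SD.

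The LPS comparisons ask which genes of the macrophage respond to LPS in each medium. With the 4 media averaged, genes of secreted inflammatory mediators were among those with the largest rises. Il6, an acute-phase cytokine, rose by 9.30 ± 0.09 (631-fold). Cxcl9, which attracts T cells, rose by 8.23 ± 0.13 and Cxcl11 by 7.71 ± 0.10. Il1a rose by 7.39 ± 0.12, and Socs3, a brake on cytokine signalling, by 7.12 ± 0.25. The interferon-inducible GTPase gene Iigp1 rose by 6.88 ± 0.21. Among the genes that fell were Cd300lb, an activating surface receptor (-5.05 ± 0.09), the transcription factors Sox4 (-4.86 ± 0.14), Lyl1 (-4.23 ± 0.15) and Cebpa (-3.91 ± 0.09), and Cnr2, a cannabinoid receptor (-3.85). Many of these genes lie at the bottom of the scale in one state, where background sets the value, so large folds measure the distance from background.

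All 16 tested members of the inflammatory cytokine list rose, as did all 19 chemokines and all 28 interferon response genes. Among them were Tnfsf4 (6.69), Oasl1 (6.21) and Mx2 (5.35). The adjusted p of these lists in the set test (camera) was 1.7e-14 for cytokines and 1.7e-15 for chemokines. It was 9.7e-22 for interferon response, which had an adjusted p = 0.066 with an estimated correlation. Of 26 effector enzyme and acute-phase genes 21 rose and 1 fell, with Ptgs2, the inducible cyclooxygenase (6.30), Hdc (5.78) and Ptx3 (4.68) among the risers. Antigen presentation and costimulation rose in 21 of 22 genes, with Cd40 at 5.14 and Cd274 at 3.13. The list of negative feedback on Tlr4 held 18 genes that rose, such as Cish (5.27) and Nfkbiz (4.17), and 4 that fell, among 23. Toll-like receptor signalling had 26 higher and 3 lower of 30. Adjusted over the list alone its lower genes numbered 4, while in every other list given for LPS the counts adjusted over the list alone were equal to those over all genes. Apoptosis and survival had 14 higher and 5 lower of 22, with Gadd45b at 3.59.

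In the average of the media with LPS the cell cycle, lysosome and NRF2 lists passed as lower and the amino acid list as higher, and none of these calls held with an estimated correlation. By medium the lysosome list passed in all 4, the cell cycle list in all but human serum, the NRF2 list in mouse and human serum only, where it also held with an estimated correlation, and the amino acid list in no serum and calf serum only. Of 29 cell cycle genes 25 fell and 3 rose, and the mitotic activator Cdc20 changed by -2.32 ± 0.17 (list adjusted p 0.0035, and adjusted p = 0.23 with an estimated correlation). With arrays centred on their medians 23 fell and 3 rose, and with quantile normalization again 25 and 2. Of 25 lysosome and autophagy genes 19 fell and 2 rose, as many with quantile normalization and 14 and 7 with arrays centred. Tfeb, a master regulator of lysosomal genes, changed by -2.31 ± 0.11 (list adjusted p 0.0045, and adjusted p = 0.17 with an estimated correlation). The antioxidant and haem list of NRF2 targets had 15 lower and 3 higher of 22, against 15 and 2 with quantile normalization and 11 and 4 with arrays centred. In it the iron exporter gene Slc40a1 changed by -2.90 ± 0.10 and Gclc by -1.37 (list adjusted p 0.037, and adjusted p = 0.066 with an estimated correlation). In the amino acid and integrated stress response list 16 genes rose, such as Nupr1 (1.81), and 5 fell, out of 28 (14 and 8 with quantile normalization, 16 and 4 with arrays centred), with a list adjusted p of 0.032 and adjusted p = 0.46 with an estimated correlation. The list medians kept their sign with both scalings.

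The 8 fixed LPS genes rose in each medium alone. Tnf rose by 4.96 in no serum, 4.56 in calf, 3.06 in mouse and 2.96 in human serum, each ± 0.09. In that order Il6 rose by 9.60, 9.37, 9.0 and 9.24 (± 0.18), Il1b by 5.90, 6.46, 5.25 and 4.73 (± 0.16), and Il12b, a subunit of interleukins 12 and 23, by 6.66, 4.21, 1.89 and 2.44 (± 0.30). Il10, an anti-inflammatory cytokine, rose by 3.26, 3.62, 5.67 and 5.36 (± 0.22), and Nos2, the inducible nitric oxide synthase, by 4.30, 4.77, 4.86 and 4.24 (± 0.20). Cxcl10 rose by 4.39, 5.93, 5.88 and 5.49 (± 0.22) and Ifnb1, the beta interferon, by 7.45, 5.12, 4.11 and 6.34 (± 0.32). Averaged over the media these 8 genes rose by 3.88 ± 0.05 (Tnf), 5.59 ± 0.08 (Il1b), 3.80 ± 0.15 (Il12b), 4.48 ± 0.11 (Il10), 4.54 ± 0.10 (Nos2), 5.42 ± 0.11 (Cxcl10) and 5.76 ± 0.16 (Ifnb1), with Il6 as given. Cytokines and chemokines passed the set test in all 4 media. So did the interferon list, with an estimated-correlation p of 0.049 in no serum, 0.052 in calf, 0.029 in mouse and 0.032 in human serum.

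By limma, 2333 genes were higher and 4609 lower with LPS in no serum, 2446 and 4459 in calf, 2103 and 3984 in mouse, and 2165 and 4180 in human serum. For the average the numbers were 3404 and 5957. More genes were lower than higher in each. Quantile normalization again kept this excess, with 2545 higher and 4268 lower in no serum, 2770 and 4169 in calf, 2370 and 3732 in mouse, 2447 and 3937 in human serum, and 3755 and 5549 for the average. With arrays centred on their medians, which by itself evens out the directions, the counts were 3229 higher and 3296 lower in no serum, 3581 and 3017 in calf, 2843 and 2769 in mouse, 2987 and 2885 in human serum, and 4544 and 4478 for the average. Centring moved the median of all genes, -0.19 in no serum and -0.15 in mouse serum, upward by 0.15 to 0.19. In all 4 media 1516 genes were higher and 2802 lower, against 15.9 and 209 expected if the calls in the media were independent, and 88 genes had calls in opposite directions in at least a pair of media. Across genes the LPS changes of any pair of media correlated at Pearson's r of 0.899 to 0.941. This does not measure their size. The slope on the changes in no serum was 0.944 for calf, 0.830 for mouse and 0.854 for human serum, and noise also lowers a slope.

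**Figure D1:**
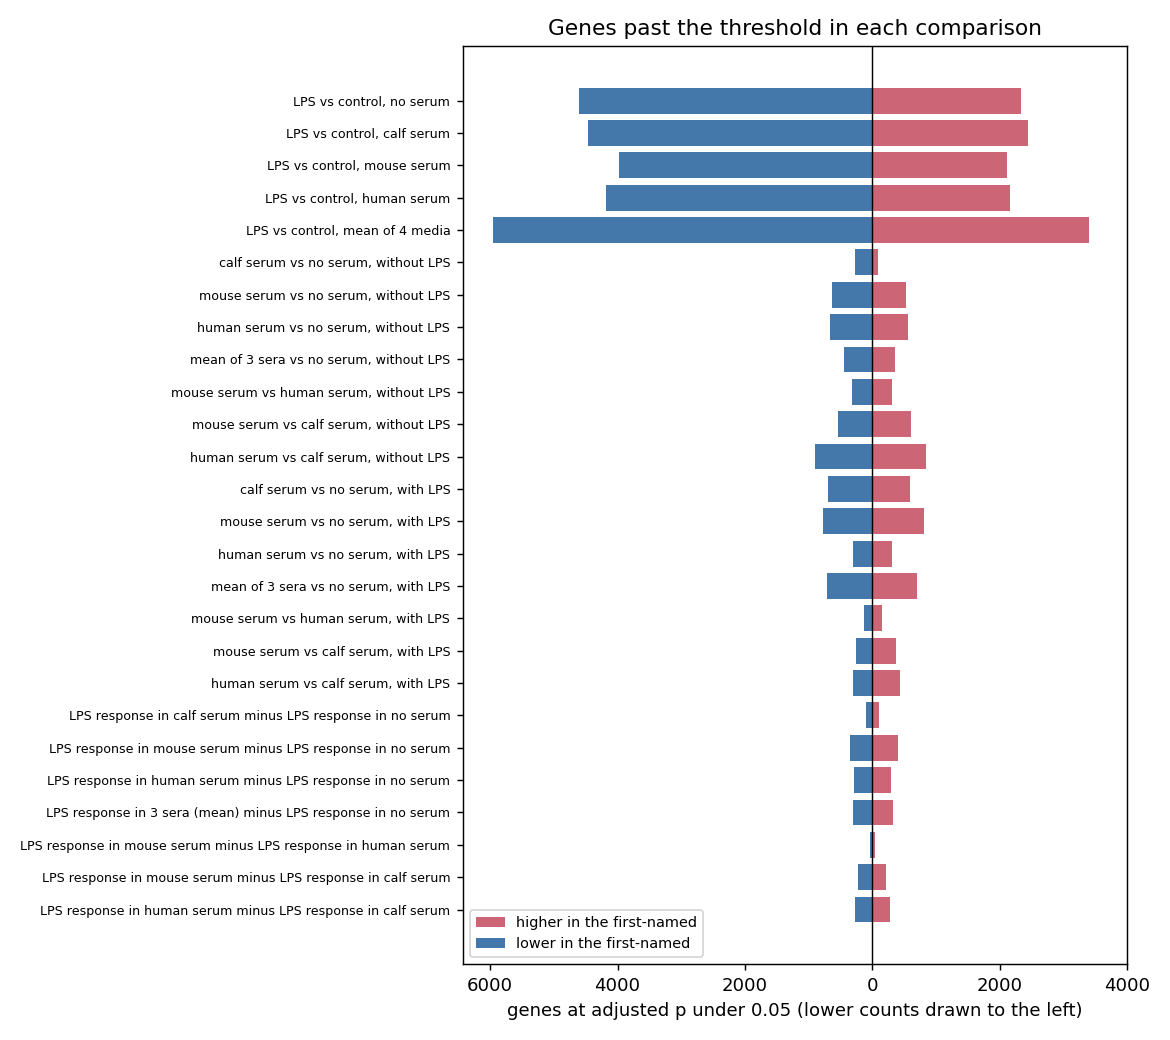
Number of genes with an adjusted p under 0.05 in each of the 26 comparisons, higher to the right and lower to the left. LPS in 1 medium gave at least 2103 higher genes, whereas calf serum against no serum without LPS gave 82.

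The comparisons of serum with no serum in unstimulated cells ask what serum itself does to macrophage expression. In calf serum the amino acid and integrated stress response fell. This programme is switched on by shortage of amino acids and by other stresses of the cell. Chac1, which degrades glutathione, changed by -2.67 ± 0.37, the amino acid transporter genes Slc1a4 and Slc7a5 by -2.29 ± 0.26 and -1.79 ± 0.19, and the stress regulators Nupr1 and Trib3 by -1.92 ± 0.09 and -1.84 ± 0.24. In the list 24 of 28 genes fell and none rose, 26 when adjusted over the list alone, with a list adjusted p of 1.8e-52. Several inflammatory genes fell as well, among them Ptgs2 (-2.01 ± 0.28), Cxcl2 (-1.58 ± 0.11), Cxcl10 (-1.54 ± 0.22) and the growth factor gene Csf1 (-1.24 ± 0.14). Id3, a target of bone morphogenetic protein signalling, rose by 2.60 ± 0.17, the chemokine gene Ccl2 by 1.44 ± 0.19 and Idi1 of sterol synthesis by 1.08 ± 0.17.

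Several lists passed the set test in calf serum without LPS. Of 21 cholesterol biosynthesis genes 2 rose over all genes and 12 adjusted over the list alone (list adjusted p 2.3e-09). TGF-beta response rose in 5 of 17 genes (7 adjusted over the list alone) and the SRF cytoskeletal targets in 5 of 21 (6 adjusted over the list alone). Negative feedback on Tlr4 fell in 8 of 23 genes, with 10 lower and 2 higher adjusted over the list alone. Inflammatory cytokines fell in 5 of 16 (6 adjusted over the list alone), apoptosis and survival in 6 of 22 (8 adjusted over the list alone) and metal handling in 4 of 12 (5 adjusted over the list alone). The limma count was 82 higher and 267 lower genes, and it lay between 112 and 334 when 1 array or experiment was left out. Fkbp5 (0.26), Hmox1 (0.17), Cd14 (-0.13) and Tlr4 (-0.16) had no call. Neither had Abca1, a cholesterol exporter (-0.27, p 0.11), although it passed with the experiment as a block (0.045) and without calf serum replicate I (-0.35, p 0.036).

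In mouse serum without LPS the immediate early and NRF2 lists were higher. Among single genes Cxcl3, a neutrophil attractant, rose by 4.05 ± 0.29, and Thbs1, the matrix glycoprotein thrombospondin, by 3.21 ± 0.16 from a level of 8.25 to 11.46. The TGF-beta target Pmepa1 rose by 3.65 ± 0.13, the Notch ligand gene Jag1 by 2.81 ± 0.11 and Olr1, a scavenger receptor, by 2.77 ± 0.28. Rasgrp3 (-2.71 ± 0.32), Calhm6 (-2.54 ± 0.11) and Hdac9 (-2.45 ± 0.18) fell. Cd14, which hands LPS to Tlr4, rose by 1.18 ± 0.08, while Tlr4 changed by -0.38 ± 0.07. Hmox1, which degrades haem, rose by 0.79 ± 0.10 and Fkbp5, a glucocorticoid target, by 1.90 ± 0.18. Abca1 had no call (-0.23, p 0.11).

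In mouse serum without LPS the serum response and immediate early list rose in 17 of 27 genes (18 adjusted over the list alone), including Nr4a1 (2.51) and the phosphatase gene Dusp5 (2.50), with a list adjusted p of 1.2e-18. NRF2 and haem targets had 12 higher and 2 lower of 22 (13 and 3 adjusted over the list alone), with Trem1 at 2.76, the cystine transporter gene Slc7a11 at 1.94 and Gclc at 1.56 (list adjusted p 4.9e-10). Glucocorticoid response had 10 higher and 2 lower of 22 (12 and 2 adjusted over the list alone), with Errfi1 at 1.91 and Il1r2 at 1.62. TGF-beta response had 8 higher and 2 lower of 17 (10 and 2 adjusted over the list alone). Growth factors and receptors had 5 higher and 2 lower of 19 (8 and 2 adjusted over the list alone), with Met at 2.40 and Vegfa at 2.00, and SRF targets had 6 higher of 21 (7 adjusted over the list alone). Markers of erythroid cells and megakaryocytes passed as higher too, with 2 of the 4 tested genes higher, as many adjusted over the list alone, and Ppbp, a platelet chemokine gene, at 2.27 ± 0.21. The interferon list passed as lower, with 2 of 28 genes past the threshold (4 adjusted over the list alone) and adjusted p = 0.71 with an estimated correlation. The limma count was 527 higher and 629 lower, and 666 to 1028 in total when 1 array or experiment was left out.

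Human serum without LPS raised the immediate early list as well. Thbs1 rose by 3.06 ± 0.16, Dusp5 by 2.65 ± 0.12, Id3 by 2.48 ± 0.17 and Phlda1 by 2.47 ± 0.20. Hbegf, a growth factor gene, rose by 2.17 and Il1rn, the interleukin 1 receptor antagonist, by 2.01. Gpr155 (-2.63 ± 0.39), Fam214a (-2.54 ± 0.28) and Sesn1, a p53 target (-2.27 ± 0.31), fell. Cd14 rose by 1.20 ± 0.08. Fkbp5 passed at 0.58 ± 0.18 (p 0.044), and not without human serum replicate G (p 0.070) or I (0.209) or no-serum replicate G (0.185) or I (0.169). Hmox1 had no call (-0.25, p 0.13) except with the experiment as a block (0.045), and neither Tlr4 (-0.14) nor Abca1 (-0.21) had one.

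The serum response and immediate early list rose in 16 of 27 genes in human serum without LPS and fell in 1 (17 and 1 adjusted over the list alone; list adjusted p 2e-18). SRF cytoskeletal targets rose in 10 of 21 (13 adjusted over the list alone), cholesterol biosynthesis in 7 of 21 (7 higher and 1 lower adjusted over the list alone) and glycolysis and hypoxia in 6 of 23 (6 higher and 1 lower adjusted over the list alone). Effector enzymes rose in 8 of 26 and fell in 1 (9 and 1 adjusted over the list alone). Growth factors and receptors, with Met at 2.17, had 7 higher and 1 lower of 19, the same adjusted over the list alone. In human serum the amino acid and integrated stress response rose in 9 of 28 genes (14 adjusted over the list alone), with adjusted p = 0.13 with an estimated correlation. The limma count was 557 higher and 670 lower genes, 1227 in all, and 803 without no-serum replicate H. It lay between 537 and 1013 when 1 array or experiment was left out.

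The average of the 3 sera without LPS weighs the sera equally, so that a gene can pass in it without a change in each serum. In calf serum alone Cxcl3 (-0.31), Thbs1 (0.17), Dusp5 (0.21) and Nr4a1 (0.68) had no call. In the average Id3 rose by 2.25 ± 0.14, Thbs1 by 2.15 ± 0.13, Cxcl3 by 2.02 ± 0.24, Dusp5 by 1.79 ± 0.10, Nr4a1 by 1.76 ± 0.24 and Jag1 by 1.72 ± 0.09. Ptger3, a prostaglandin receptor (-1.85 ± 0.25), Bmp2 (-1.73 ± 0.19), Ffar2, a short-chain fatty acid receptor (-1.65 ± 0.25), and Calhm6 (-1.50 ± 0.09) fell. Cd14 rose by 0.75 ± 0.06 and Fkbp5 by 0.91 ± 0.15. Tlr4 changed by -0.23 ± 0.06 (p 0.019), and had no call without no-serum replicate G (0.092) or H (0.1). Abca1 changed by -0.24 ± 0.07 (p 0.041). It had no call without any 1 of the no-serum replicates G, H and I (0.216, 0.080 and 0.109), calf replicates G and H, human replicates G and H, or mouse replicates H and I (0.052 to 0.064). Hmox1 had no call (0.24, p 0.088) except with the experiment as a block (0.025).

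In the average of the sera the serum response and immediate early list rose in 16 of 27 genes, as many adjusted over the list alone (list adjusted p 2.7e-18). SRF targets rose in 8 of 21 (10 adjusted over the list alone), TGF-beta response had 8 higher and 2 lower of 17 (as many adjusted over the list alone), and NRF2 and haem targets 8 higher and 2 lower of 22 (10 and 5 adjusted over the list alone). Cholesterol biosynthesis rose in 3 of 21 genes (4 adjusted over the list alone) and growth factors in 7 of 19 with 2 lower (as many adjusted over the list alone). Erythroid and megakaryocyte markers were higher in 2 of 4, as many adjusted over the list alone. For the amino acid and integrated stress response, lower in calf and higher in human serum, 8 of 28 genes were lower and 1 higher (13 and 1 adjusted over the list alone), with adjusted p = 0.28 with an estimated correlation. Glucocorticoid response passed as higher (list adjusted p 0.033, and adjusted p = 0.082 with an estimated correlation), with a mean of 0.07 but a median of -0.01, which was 0.01 with arrays centred and -0.03 with quantile normalization. Its members numbered 5 higher and 2 lower of 22 (5 and 3 adjusted over the list alone). By limma 361 genes were higher and 442 lower, 803 in all. That total was 472 without no-serum replicate H and lay between 347 and 812 when 1 array or experiment was left out.

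**Figure D2:**
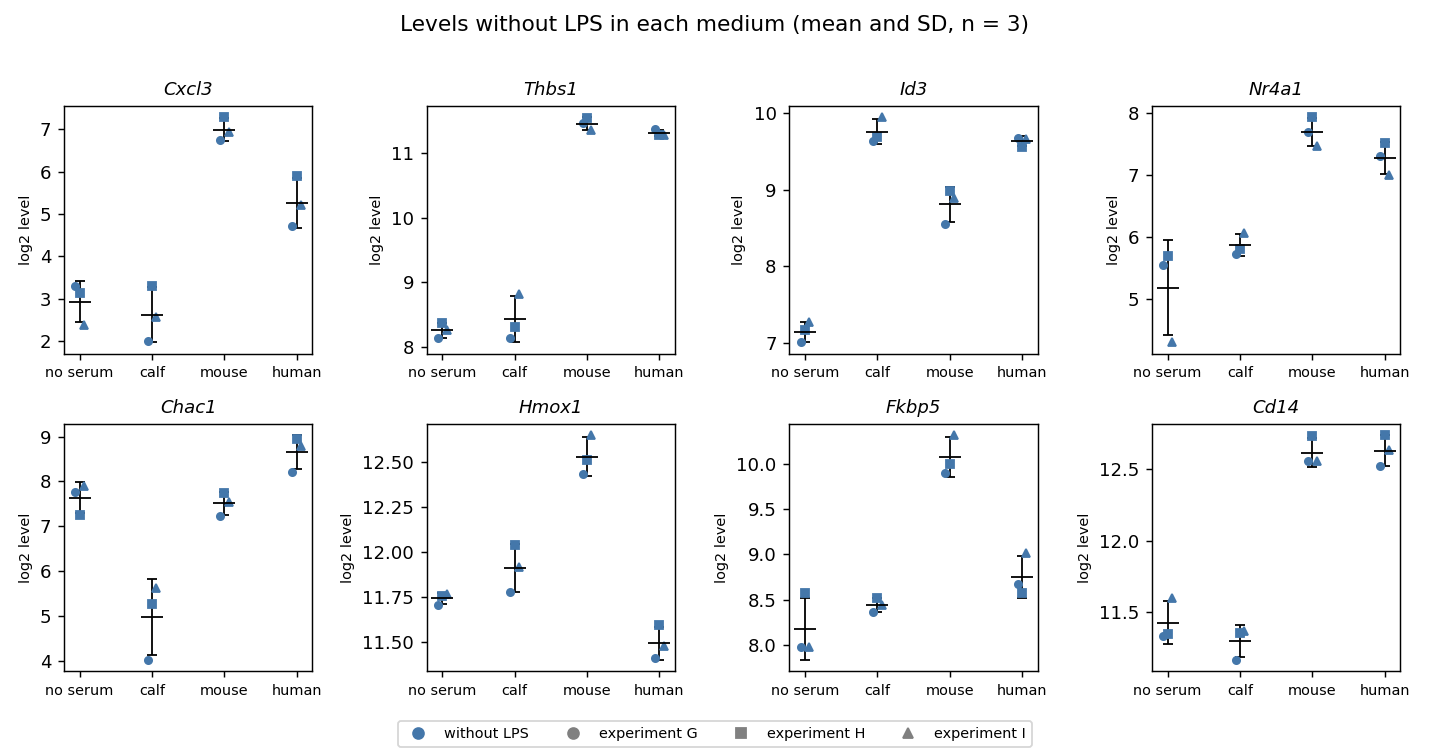
Log2 levels without LPS of 8 genes in no serum and calf, mouse and human serum, with the 3 experiments as points and the mean and SD as bars. Thbs1 has a mean of 8.25 in no serum and 11.46 in mouse serum, and Chac1 has its lowest mean, 4.97, in calf serum.

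Comparing the sera with one another asks whether the kind of serum matters. Only the calf serum is described as fetal, so in its comparisons species cannot be told apart from fetal origin. No serum lots are distinguished here, so a difference between lots cannot be told apart from one between species. Without LPS, mouse serum differed from human serum in antioxidant and stress genes. Hmox1 was higher in mouse serum by 1.03 ± 0.10, Fkbp5 by 1.32 ± 0.18, Trem1 by 2.29 ± 0.21, and the glutathione synthesis genes Gclc and Gclm by 1.31 and 1.19. Lower in mouse serum were Ccl3, a chemokine gene (-2.04 ± 0.18), Hbegf (-1.75) and Cass4, an adhesion adaptor gene (-2.52 ± 0.45). NRF2 and haem targets were higher in 13 of 22 genes (15 higher and 1 lower adjusted over the list alone; list adjusted p 3.9e-18). The amino acid and integrated stress response was lower in 15 and higher in 1 of 28 (23 and 2 adjusted over the list alone; list adjusted p 1.8e-18). SRF targets were lower in 4 of 21 (6 adjusted over the list alone) and cholesterol biosynthesis in 4 of 21 (5 adjusted over the list alone). Markers of other cells also passed as higher in mouse serum, erythroid and megakaryocyte with 2 of 4 genes higher, as many adjusted over the list alone, and neutrophil with 0 of 6 past the threshold either way, with adjusted p = 0.062 and 0.26 with an estimated correlation. Cd14 (-0.01), Abca1 (-0.01) and Tlr4 (-0.24, p 0.063) had no call, although Tlr4 passed without mouse serum replicate H (0.049). By limma 302 genes were higher and 317 lower in mouse serum, and the total lay between 208 and 530 when 1 array or experiment was left out.

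Without LPS, calf serum differed from the other sera in more genes than these differed from each other. Against calf serum, mouse serum raised Cxcl3 by 4.36, Olr1 by 3.94 and Thbs1 by 3.04, Cd14 by 1.32 ± 0.08, Fkbp5 by 1.63 ± 0.18 and Hmox1 by 0.62 ± 0.10. Hpgd, which degrades prostaglandins, was lower (-3.17). Human serum raised Chac1 by 3.68, Ptgs2 by 3.51, Aqp9, a glycerol channel gene, by 3.07 and Cd14 by 1.33 ± 0.08 over calf serum, and lowered Gpr155 (-3.30), Fam214a (-2.85) and Hmox1 (-0.42 ± 0.10). All 28 amino acid and integrated stress response genes were higher in human than in calf serum, as many adjusted over the list alone (list adjusted p 4.2e-42). In mouse serum 16 were higher than in calf serum (24 adjusted over the list alone). Immediate early genes were higher in 14 of 27 in mouse serum, as many adjusted over the list alone, and in human serum in 14 with 1 lower (17 and 3 adjusted over the list alone). Glucocorticoid response in mouse against calf serum had 12 higher and 4 lower of 22 (13 and 4 adjusted over the list alone). Effector enzymes were higher in 10 of 26 in mouse serum and in 10 in human serum (10 and 11 adjusted over the list alone). Abca1 (0.04 and 0.05 in mouse and human serum) and Tlr4 (-0.22 and 0.02) had no call, nor had Fkbp5 in human against calf serum (0.31). The limma counts were 597 higher and 538 lower in mouse serum and 837 and 894 in human serum.

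The comparisons with LPS ask whether serum changes the state macrophages reach with LPS. With LPS some cytokine genes were lower and others higher in serum. Averaged over the 3 sera, Csf2, the granulocyte-macrophage growth factor, changed by -4.50 ± 0.18 and Il23a, the private subunit of interleukin 23, by -4.48 ± 0.20. Il12b changed by -3.26 ± 0.25, Ifnb1 by -2.14 ± 0.26, the transcription repressor gene Gfi1 by -3.05 ± 0.34, Tslp by -1.98 ± 0.17 and Il12a by -1.56. Il23a had a level of 9.34 ± 0.48 with LPS in no serum and 5.16 ± 0.53, 3.93 ± 0.03 and 5.46 ± 0.51 in calf, mouse and human serum, against 3.32 ± 0.19 in no serum without LPS. Il33, a cytokine of barrier tissues, rose by 3.54 ± 0.15, Irf2bpl by 2.25 ± 0.13, Nek6 by 1.90 ± 0.11, Il10 by 1.42 ± 0.18 and Dusp1, a phosphatase that ends kinase signalling, by 1.53 ± 0.05.

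In that average with LPS, 11 of 16 inflammatory cytokines fell and none rose (12 adjusted over the list alone; list adjusted p 3e-17). Of the amino acid and integrated stress response 20 genes were lower and 1 higher of 28 (24 and 1 adjusted over the list alone; list adjusted p 3e-17), with Ppp1r15a at -1.53 ± 0.12 and Ddit3 at -1.10. Apoptosis and survival had 7 lower and 2 higher of 22 (10 and 2 adjusted over the list alone), with Gadd45a at -1.65. SRF targets had 7 higher and 1 lower of 21 (9 and 1 adjusted over the list alone), with Zyx at 1.14 and Cnn2 at 0.96. The metal list rose in 4 of 12, as many adjusted over the list alone, with the metallothioneins Mt2 at 1.12 and Mt1 at 0.91. Macrophage identity passed as higher with 4 higher and 1 lower of 26 (6 and 1 adjusted over the list alone), and adjusted p = 0.20 with an estimated correlation. Abca1 changed by -0.53 ± 0.07 and Tlr4 by -0.34 ± 0.06. Cd14 changed by 0.24 ± 0.06 (p 0.013), with no call without no-serum replicate G (0.112) or I (0.052), and Hmox1 (-0.05) and Fkbp5 (0.04) had none. By limma 698 genes were higher and 721 lower, and the total lay between 760 and 1476 when 1 array or experiment was left out.

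**Figure D3:**
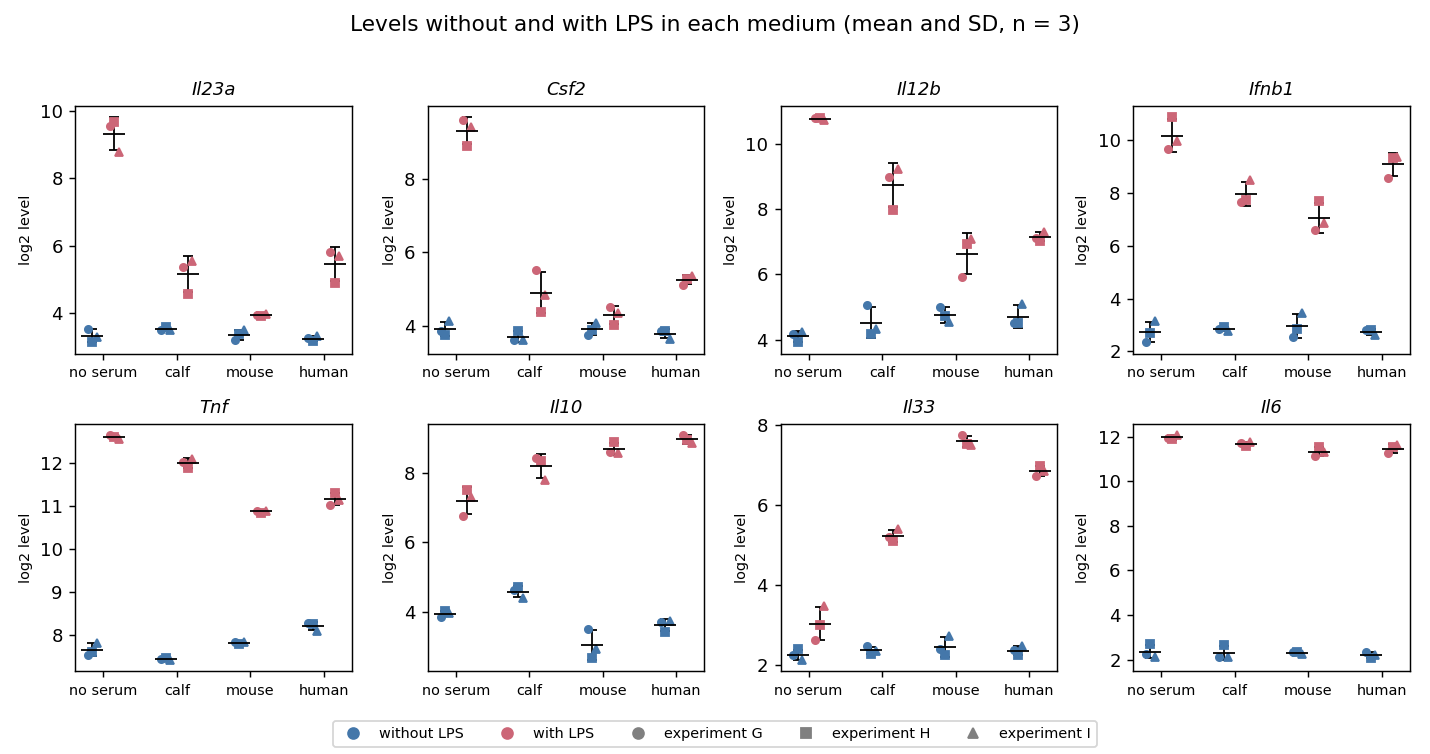
Log2 levels of 8 cytokine genes without LPS and with LPS in the 4 media, with the 3 experiments as points and the mean and SD as bars. With LPS, Il23a has a mean of 9.34 in no serum and 3.93 in mouse serum, and Il33 has means of 3.03 and 7.60.

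In each serum alone Csf2, Il23a and Il12b were lower with LPS. In calf serum Csf2 changed by -4.41 ± 0.22, Il23a by -4.17 ± 0.25 and Il12b by -2.03 ± 0.30, while Trib3 changed by -2.37 ± 0.24 and Ddit4 by -2.24 ± 0.25. Lipg, an endothelial lipase gene, rose by 2.25 and Il33 by 2.20 ± 0.18. Of 16 inflammatory cytokines 8 fell (10 adjusted over the list alone), and of 28 amino acid and integrated stress response genes 24 fell (26 adjusted over the list alone). Macrophage identity rose in 9 of 26, as many adjusted over the list alone. SRF targets had 6 higher and 1 lower of 21 (7 and 1 adjusted over the list alone), with adjusted p = 0.064 with an estimated correlation. Abca1 changed by -0.70 ± 0.09 and Tlr4 by -0.47 ± 0.07, and Cd14 (-0.06), Hmox1 (-0.18) and Fkbp5 (0.01) had no call. By limma 589 genes were higher and 690 lower, 1279 in all, and 823 without calf serum LPS replicate H, which stood apart from the other two of its group on the fourth principal component (27.4 against 5.91 and 10.6). With only the groups compared in the fit it was 728. The total lay between 513 and 1239 when 1 array or experiment was left out.

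In mouse serum with LPS Il23a changed by -5.40 ± 0.25, Csf2 by -5.03 ± 0.22, Il12b by -4.13 ± 0.30 and Ifnb1 by -3.12 ± 0.32. Il33 rose by 4.57 ± 0.18, Dusp1 by 1.83 ± 0.06 and Il10 by 1.5 ± 0.22. The immediate early genes parted, with Fos at 2.33 ± 0.16, Nr4a1 at 2.03 ± 0.30 and Nr4a3 at -2.58 ± 0.35. Inflammatory cytokines fell in 11 of 16 (12 adjusted over the list alone), while NRF2 and haem targets rose in 9 of 22 (9 higher and 1 lower adjusted over the list alone), with Srxn1 at 0.88 ± 0.08. PPAR and lipid storage rose in 8 of 21 (9 adjusted over the list alone). Of 28 amino acid and integrated stress response genes 16 were lower and 1 higher (18 and 1 adjusted over the list alone), with adjusted p = 0.092 with an estimated correlation. Chemokines had 6 lower and 1 higher of 19, as many adjusted over the list alone, with adjusted p = 0.23 with an estimated correlation. Abca1 changed by -0.60 ± 0.09, Tlr4 by -0.37 ± 0.07 and Cd14 by 0.44 ± 0.08, and Fkbp5 (0.23) had no call. Hmox1 passed at 0.30 ± 0.10 (p 0.044), but not without mouse serum LPS replicate G (0.058) or I (0.268) or no-serum LPS replicate G (0.157), H (0.077) or I (0.065). By limma 804 genes were higher and 775 lower.

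In human serum with LPS Csf2 changed by -4.06 ± 0.22, Il23a by -3.88 ± 0.25 and Il12b by -3.62 ± 0.30. Il33 rose by 3.84, Slamf1 by 2.34, Hbegf by 2.32, Egr1, a growth-response factor, by 1.81 ± 0.17 and Il10 by 1.78 ± 0.22. Inflammatory cytokines fell in 7 of 16 (9 adjusted over the list alone). The immediate early list had 11 higher and 3 lower of 27 (13 and 3 adjusted over the list alone), SRF targets 7 higher of 21 (8 adjusted over the list alone) and growth factors 4 higher and 2 lower of 19 (8 and 2 adjusted over the list alone). Negative feedback on Tlr4 had 6 higher of 23 (7 adjusted over the list alone), with adjusted p = 0.081 with an estimated correlation. Cd14 passed at 0.34 ± 0.08 but not without no-serum LPS replicate G (0.054), and Abca1 at -0.29 ± 0.09 (p 0.047) but not without any 1 of the 3 human serum or 3 no-serum LPS arrays (0.051 to 0.182). Hmox1 had no call (-0.28, p 0.11) except with the experiment as a block (0.034), and neither had Tlr4 (-0.19) or Fkbp5 (-0.10). By limma 306 genes were higher and 311 lower, 617 in all, and 406 without human serum LPS replicate G. The total lay between 264 and 511 when 1 array or experiment was left out.

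Between the sera with LPS, mouse serum differed from human serum in Ch25h, which makes 25-hydroxycholesterol (1.65 ± 0.25), Fos (1.43 ± 0.16), Hmox1 (0.59 ± 0.10), Ifnb1 (-2.02 ± 0.32) and the adhesion molecule gene Sele (-1.99 ± 0.20). NRF2 and haem targets were higher in 7 of 22 genes (11 adjusted over the list alone; list adjusted p 4.6e-12), with Srxn1 at 0.65 and Gclm at 0.62. Inflammatory cytokines were lower in 4 of 16 (7 adjusted over the list alone). The amino acid and integrated stress response was lower in 8 of 28 (15 lower and 1 higher adjusted over the list alone), with adjusted p = 0.057 with an estimated correlation. Cd14 (0.10), Fkbp5 (0.33) and Tlr4 (-0.18) had no call. Abca1 had none (-0.31, p 0.057) except with the experiment as a block (0.023) or without mouse serum LPS replicate I (0.018). By limma 152 genes were higher and 130 lower, 282 in all. That total was 164 without human serum LPS replicate G or mouse serum LPS replicate H, 143 without human H, 161 without human I, 181 without mouse I and 30 without experiment I.

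Calf serum again differed from both others with LPS. Against calf serum, mouse serum had more Ddit4, a stress-induced inhibitor of growth signalling (2.60 ± 0.25), more Il33 (2.37), and less Il12b (-2.10 ± 0.30), Gfi1 (-2.22) and Tnf (-1.13 ± 0.09). Human serum had more Ddit4 (2.36 ± 0.25), Trib3 (2.32 ± 0.24) and Rnf125 (2.43), and less Hspa1b, a heat shock protein gene (-2.01). The amino acid and integrated stress response was higher in 23 of 28 genes in human serum (26 adjusted over the list alone) and in 13 with 1 lower in mouse serum (18 and 1 adjusted over the list alone). Glucocorticoid response was higher in 10 of 22 in human serum (11 adjusted over the list alone) and in 10 with 1 lower in mouse serum (11 and 1 adjusted over the list alone). Inflammatory cytokines in mouse serum were lower in 5 and higher in 1 of 16 (7 and 1 adjusted over the list alone). Cd14 was higher by 0.50 ± 0.08 and 0.40 ± 0.08 in mouse and human serum. Hmox1 was higher in mouse serum (0.48 ± 0.10) and Abca1 in human serum (0.41 ± 0.09), and Tlr4 passed in human serum at 0.28 ± 0.07 but not without calf LPS replicate H (0.146) or human LPS replicates G (0.095) or H (0.089). Fkbp5 (0.22 in mouse and -0.11 in human serum), Abca1 and Tlr4 in mouse serum (both 0.10) and Hmox1 in human serum (-0.11) had no call. The limma counts were 376 higher and 263 lower in mouse serum, 639 in all, and 433 and 306 in human serum, 739 in all. Without calf serum LPS replicate H, the array apart from its group, each total was 503. With only the groups compared in the fit the totals were 308 and 538, and the human serum total was 475 without human serum LPS replicate H.

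The last comparisons ask whether the LPS response itself differs between media, as a difference between differences. Averaged over the sera, the responses of 5 cytokine genes to LPS were smaller in serum, with differences of -4.54 for Il23a, -4.38 for Csf2, -3.81 ± 0.35 for Il12b, -2.25 ± 0.37 for Ifnb1 and -1.43 ± 0.10 for Tnf. Responses were larger in serum by 3.40 for Il33, 1.62 ± 0.25 for Il10 and 1.37 ± 0.25 for Cxcl10. The call of Cxcl10 was lost without experiment G (adjusted p 0.063) or I (0.067). Cxcl10 reached 13.79 to 13.85 with LPS in the 4 media, so its responses differed through the level without LPS. That level was 9.44 in no serum and 7.90, 7.91 and 8.36 in calf, mouse and human serum. The highest value on any array was 14.84, and whether the scale limits Cxcl10 with LPS was not tested. The difference passed no threshold for Il6 (-0.39, p 0.34), Il1b (-0.42, p 0.22) or Nos2 (0.32, p 0.55). Inflammatory cytokines had 7 smaller and 1 larger response of 16 (9 and 2 adjusted over the list alone; list adjusted p 8.8e-13). Immediate early genes had 8 smaller and 1 larger of 27 (10 and 1 adjusted over the list alone), TGF-beta response 6 smaller of 17 (6 smaller and 2 larger adjusted over the list alone) and the metal list 4 larger of 12 (7 adjusted over the list alone). The amino acid and integrated stress response had 4 smaller and 1 larger of 28 (8 and 2 adjusted over the list alone), with adjusted p = 0.28 with an estimated correlation.

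For single sera against no serum, Tnf had a smaller response in mouse serum (-1.90 ± 0.13) and human serum (-2.0 ± 0.13), and its difference of -0.40 in calf serum had no call (p 0.13). Il6 (-0.59 to -0.13) and Nos2 (-0.53 to 0.62) had no call in any of the 7 differences between media. Inflammatory cytokines had 9 smaller and 2 larger responses of 16 in mouse serum (11 and 2 adjusted over the list alone), 8 and 1 in human serum (as many adjusted over the list alone) and 3 smaller in calf serum (7 smaller and 3 larger adjusted over the list alone). By limma 106 genes had a larger and 106 a smaller LPS response in calf serum, 401 and 360 in mouse serum, 295 and 290 in human serum, and 320 and 298 in the average. Between mouse and human serum 37 were larger and 37 smaller, 74 in all. That total was 133 with the experiment as a block and 9 without experiment I. Without human serum LPS replicate H it was 48, and without mouse serum control replicate I it was 46. NRF2 and haem targets were the list that passed between these sera, with 2 smaller responses of 22 (9 smaller and 2 larger adjusted over the list alone). The counts were 215 larger and 230 smaller for mouse against calf serum and 275 and 267 for human against calf serum.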

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

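The test of a uniformly weaker LPS stimulus given here was chosen only after the result was seen. The results below were singled out because the LPS response in one medium differed from that in another by a test of the difference itself, with n = 3 arrays per group in limma and log2 values throughout.

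Against no serum, the responses of Csf2 and Il12b to LPS were smaller in each of the 3 sera. In calf serum, where 212 genes differed, Il23a differed by -4.38, Csf2 by -4.19, the signalling brake Socs2 by -2.68, Il12b by -2.44 and Ifnb1 by -2.33. Matn2, a matrix protein gene, responded more by 3.35, Lipg by 2.35, Il33 by 2.10 and Cxcl10 by 1.53. Tnf (-0.40, p 0.13), Il10 (0.36, p 0.71) and Il1b (0.56, p 0.25) had no call, and Il1b gained one without no-serum control replicate I (0.80, p 0.025). In mouse serum, with 761 genes, Il23a differed by -5.43, Csf2 by -5.02, Il12b by -4.77, Ifnb1 by -3.33 and Tnf by -1.90. Larger there were the responses of Il33 (4.37), Ppp1r3b, a regulator of glycogen synthesis (2.75), the histone deacetylase gene Hdac9 (2.65), Il10 (2.41) and Cxcl10 (1.49), and Il1b had no call (-0.65, p 0.092) but gained one without mouse serum control replicate I (-0.82, p 0.024).

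In human serum 585 genes differed from no serum in their LPS response. Il12b differed by -4.22, Csf2 by -3.93, Cass4 by -3.87, Tnf by -2.0 and Il1b by -1.17, and Il33 by 3.73, Sesn1 by 2.59, the lymphocyte receptor gene Slamf1 by 2.52, Il10 by 2.10 and Cxcl10 by 1.10. Ifnb1 had no call (-1.10, p 0.19). In the average of the sera, with 618 genes, the differences were -4.54 for Il23a, -4.38 for Csf2, -3.81 for Il12b, -2.25 for Ifnb1 and -1.43 for Tnf, and 3.40 for Il33, 2.09 for Tspyl3, 2.01 for the transcription factor gene Pou2f2, 1.62 for Il10 and 1.37 for Cxcl10. Cxcl10 in human serum kept its call only without human serum control replicate H among the 12 arrays left out in turn, and its adjusted p was otherwise 0.059 to 0.116. Without experiment G or I, Cxcl10 had no call in calf (0.109 and 0.176), mouse (0.098 and 0.067) or human serum (0.335 and 0.392). Nor had it one in the average (0.063 and 0.067). Its levels with LPS were nearly the same in all media, so these differences lie in its level without LPS. Tspyl3 had no call without no-serum LPS replicate G (0.119) or I (0.143), or no-serum control replicate G (0.052), H (0.084) or I (0.080).

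The sera also differed from one another in the response. Between mouse and human serum, with 74 genes, Ch25h differed by 3.14, Zfp3 by 1.89, Hdac9 by 1.87, Mettl27 by -2.39, Asb4 by -2.28, the hepatocyte growth factor gene Hgf by -2.27 and Ifnb1 by -2.23. Ifnb1 had no call without mouse LPS replicate G (0.055), human LPS replicate H (0.058) or I (0.056), or mouse control replicate I (0.068). Mettl27 had none without 10 of the 12 arrays (0.051 to 0.137), the other two being human LPS replicate I and mouse LPS replicate G. Whichever experiment was left out, Hgf (0.053 to 0.070), Ifnb1 (0.070 to 0.492) and Mettl27 (0.209 to 0.247) had no call. Asb4 had none without experiment G (0.083) or H (0.376). Zfp3 had none without G (0.247) or I (0.121), and Hdac9 none without H (0.065). Ch25h kept its call throughout. Between mouse and calf serum, with 445 genes, Gpr155 differed by 3.43, Rasgrp3 by 2.98, the receptor gene Gpr34 by 2.95 and Il10 by 2.05. Smaller were Cxcl3 (-3.54), Ptgs2 (-3.14), Cxcl1 (-3.05), Il12b (-2.33), Tnf (-1.50) and Il1b (-1.21). Between human and calf serum, with 542 genes, Rasgrp3 differed by 3.66, Gpr155 by 3.50, Gpr34 by 3.16 and Il10 by 1.74, and Ptgs2 by -3.57, Cass4 by -3.52, Matn2 by -2.82, Il12b by -1.77, Il1b by -1.73 and Tnf by -1.60. Il12b in that comparison had no call without calf control replicate H (0.0506). Of the 66 gene differences 20 lost their call without 1 of the experiments and 0 changed direction. Besides those named, against no serum they were Ifnb1, Il12b and Matn2 in calf serum, Sesn1 and Slamf1 in human serum, and Tspyl3 in the average. Between sera they were Il1b for mouse against calf serum, and Il10, Il12b and Matn2 for human against calf serum. The rule for naming the largest changes required the same sign in experiments G, H and I. Leaving out 1 experiment therefore could not reverse those genes.

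The fall of Il23a, Csf2, Il12b and Ifnb1 with LPS in serum was weighed against technical causes. It does not rest on 1 array or experiment, since over 15 leave-outs the highest adjusted p of the 4 genes was 0.00127, and Il23a stayed between -4.87 and -4.12 and Ifnb1 between -2.39 and -1.79. A weaker LPS stimulus in serum could lower them, and was tested on the 200 genes with the largest rise (levels up to 12). Ranked by the rise in no serum their median difference was -0.224 (SE 0.0768), with 61 lower and 15 higher, and ranked by the rise in the sera -0.030 (SE 0.0614), with 36 lower and 22 higher. Both rankings use LPS arrays that also form the difference tested. Selection alone thus pulls the first median down and the second up, and the SE treats the genes as independent. Both medians lie far from the changes of the 4 genes, but these were singled out for their falls on the same arrays, so the distance decides nothing. The medians cannot decide on a partly weaker stimulus, because selection shifts them and the 200 genes went both ways. An effect of the sera on these genes in particular stays open beside a weaker stimulus.

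Other splits of the same arrays were used to ask how often chance gives as many genes. In the averaged differences in response, the real split was the 1 of 100 with the most genes, 618 against 95 in the next. The others were random draws that can keep part of the real grouping. In a split that mixes the groups, real differences between them enter the spread within groups and lower the count. The lower counts of other splits, here and below, are thus not those that chance alone would give. They do not exclude chance. The real split also had the most genes for LPS averaged over the media (9361 against 7210). So it did for the average of the sera with LPS (1419 against 425) and without LPS (803 against 404). The remaining comparisons allow 10 splits, which are too few for a share under 0.05. For the responses the real value and the highest other were 212 and 0 in calf, 761 and 0 in mouse and 585 and 0 in human serum against no serum, 74 and 1 for mouse against human, 445 and 1 for mouse against calf and 542 and 0 for human against calf serum. For LPS in 1 medium they were 6942, 6905, 6087 and 6345, each with 0. Without LPS they were 349 and 0, 1156 and 0, and 1227 and 1 for calf, mouse and human serum against no serum, and 619 and 8, 1135 and 0, and 1731 and 5 for mouse against human, mouse against calf and human against calf serum. With LPS they were, in that order, 1279 and 4, 1579 and 3, 617 and 1, 282 and 1, 639 and 2, and 739 and 1.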

How the results depend on the processing

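All alternatives were chosen before the data were examined. With the experiment as a block, 25 of the 26 counts of genes lay within 1.5 times their value, and the exception was the difference in LPS response between mouse and human serum, 74 genes, 133 with the block. That count was also 114 with the array batch as a block, 116 with the experiment as a random block, 127 with array weights and 41 without trend or robust moderation, and the cause was not tested. The replicate block changed the call of 6 of the 1172 gene results, which the report names for Abca1 and Hmox1, and Ddit4 in mouse serum without LPS lost its call (adjusted p 0.053). It changed 1 of the 268 list calls, chemokines in the LPS response in mouse serum against no serum (adjusted p 0.061).

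Fitting only the groups compared, which leaves fewer arrays to estimate the spread, gave 728 genes in place of 1279 for calf serum against no serum with LPS and 308 in place of 639 for mouse against calf serum with LPS. The other counts stayed within 1.5 times with this setting. All counts did so with no filter or a stricter filter, the mean of a gene's probe sets, each probe set tested, arrays centred and quantile normalization again, although centring moved the shares higher and lower with LPS as the report gives. Of the 1172 gene results 1145 kept their direction and side of the threshold with arrays centred, 1152 with quantile normalization, 1120 with no filter, 1024 of those left with the stricter filter, 1116 with the mean of probe sets, 1062 with only the groups compared and 1114 without trend or robust moderation.

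Stricter thresholds lower a count by construction. At least a 2-fold change left, for LPS, 2624 genes in no serum, 2556 in calf, 2190 in mouse and 2250 in human serum and 2276 in the average. Without LPS it left 68 for calf, 259 for mouse and 210 for human serum and 71 for the average against no serum, 103 for mouse against human, 269 for mouse against calf and 314 for human against calf serum. With LPS the numbers in that order were 208, 290, 145, 144, 42, 146 and 146. For the differences in LPS response, against no serum in calf, mouse and human serum and the average, and then mouse against human, mouse against calf and human against calf serum, they were 93, 318, 250, 173, 35, 211 and 222. An adjusted p under 0.01 left, in the same order, 226, 742, 649, 458, 354, 697 and 973 without LPS, 653, 872, 344, 813, 116, 348 and 385 with LPS and 96, 423, 304, 330, 29, 230 and 259 for the responses, and the 5 LPS counts stayed within 1.5 times.

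Leaving out 1 array or 1 experiment leaves fewer samples, and each lowest count came without a whole experiment. The 5 LPS counts stayed within 1.5 times. Without LPS the counts were 112 to 334 for calf serum, 666 to 1028 for mouse, 537 to 1013 for human, 347 to 812 for the average, 208 to 530 for mouse against human, 592 to 928 for mouse against calf and 852 to 1522 for human against calf. With LPS they were 513 to 1239 for calf serum, 783 to 1302 for mouse, 264 to 511 for human, 760 to 1476 for the average, 30 to 189 for mouse against human, 278 to 592 for mouse against calf and 293 to 736 for human against calf. For the differences in LPS response they were 50 to 249 for calf serum, 331 to 691 for mouse, 215 to 575 for human, 225 to 696 for the average, 9 to 72 for mouse against human, 176 to 412 for mouse against calf and 165 to 531 for human against calf. The report names the single arrays that moved a count by more than 1.5 times, and the cause of the lower counts beyond the loss of samples was not tested.

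A change of direction was rare. Except for the genes always given, naming required the same sign in experiments G, H and I. Leaving out 1 experiment therefore could not reverse the genes so named. Outside the leave-outs a change of direction touched 13 gene values, and only the 2 values of Tlr7 belong to results past the threshold in the model. With the mean of its probe sets Tlr7 was 0.25 in human serum and 0.11 in the average of the sera without LPS. With the array batch as a block, Cxcl10 was 0.0418 for the response in mouse serum against calf serum. With array weights, Tlr4 was -0.00243 for human serum against calf serum without LPS and Nos2 was -0.0106 for the response in mouse serum against calf serum. With the mean of a gene's probe sets, Abca1 was -0.0773 for mouse serum against calf serum without LPS, Fkbp5 was 0.0984 for human serum against no serum with LPS and Abca1 was -0.0367 for mouse serum against calf serum with LPS. With each probe set tested, Abca1 was -0.22 for mouse serum against calf serum without LPS, Abca1 was -0.20 for human serum against calf serum without LPS, Fkbp5 was 0.30 for human serum against no serum with LPS and Abca1 was -0.17 for mouse serum against calf serum with LPS. With quantile normalization again, Tlr4 was -0.00576 for human serum against calf serum without LPS. The adjusted p of these values ran from 0.383 to 0.992, and the cause was not tested.

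With 1 array or experiment left out, 37 values of 16 gene results without a call changed direction, with adjusted p of 0.8 to 0.998, and the cause was not tested. Their ranges over the leave-outs were as follows. Abca1 ran from -0.00974 to 0.13 for mouse serum against calf serum without LPS, from -0.0341 to 0.0207 for mouse serum against human serum without LPS. Cd14 ran from -0.13 to 0.0323 for calf serum against no serum with LPS, from -0.0711 to 0.0399 for mouse serum against human serum without LPS. Cxcl10 ran from -0.71 to 0.0262 for the response in human serum against calf serum, from -0.15 to 0.10 for the response in mouse serum against calf serum, from -0.0702 to 0.66 for the response in mouse serum against human serum. Fkbp5 ran from -0.13 to 0.14 for calf serum against no serum with LPS, from -0.25 to 0.0657 for human serum against no serum with LPS, from -0.0911 to 0.17 for the mean of 3 sera against no serum with LPS. Il12b ran from -1.01 to 0.025 for the response in mouse serum against human serum. Il6 ran from -0.45 to 0.14 for the response in human serum against calf serum. Nos2 ran from -0.26 to 0.10 for the response in human serum against no serum, from -0.16 to 0.29 for the response in mouse serum against calf serum. Tlr4 ran from -0.0367 to 0.052 for human serum against calf serum without LPS, from -0.0148 to 0.17 for mouse serum against calf serum with LPS.

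Of the 1172 gene results 415 changed their call or direction in at least 1 leave-out, and 1595 of 15738 leave-out values differed in this way. Of the 268 list calls 162 kept theirs with an estimated correlation, 258 in the directional and 259 in the mixed form of fry. Signal over background limits the low end. Probe sets at or under the filter value of 5.08 carry mostly background, so for the 96 named genes with a group mean below it, Il23a, Csf2 and Il33 among them, the fold depends on that background, and a difference between groups that both lie there was not detectable.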

Other observations

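The tests of endotoxin, of RNA carried over with serum and of centring given here were chosen only after the result was seen, as was the split of the response differences by level. LPS reached beyond the mediators the report describes. In the average of the media single genes of lipid handling changed, although the lists of cholesterol biosynthesis (adjusted p 0.27), fatty acid synthesis (0.19), LXR targets (0.47) and PPAR and lipid storage (0.52) did not pass there. Angptl4, an inhibitor of lipoprotein lipase, changed by -2.59 and the nuclear receptor gene Pparg by -2.04, while the scavenger receptor gene Olr1 rose by 4.85 and Ch25h by 4.42. Scd2 of fatty acid desaturation changed by -1.64, and Msmo1 and Lss of sterol synthesis by -1.38 and -1.25. Of sugar metabolism, Pfkfb3 rose by 2.56 and Hk2 by 2.15, while the glycolysis and hypoxia list had 9 genes higher and 11 lower of 23 and did not pass (adjusted p 0.38). Among immediate early genes Fos changed by -2.48, while Nr4a3 rose by 2.98 and Maff by 2.04. Ccl22, a chemokine gene of dendritic cells, rose by 4.72, the transcription factor gene Irf8 by 1.99 and Fcgr4, an activating antibody receptor, by 2.13.

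Calls in the set test over the 26 comparisons were counted for lists with little or no place in the report. LXR targets passed as higher in 1 and lower in 2, with 1 call held with an estimated correlation. Alternative activation passed as higher in 2 and lower in 1 (1 held), complement and Fc receptors as higher in 1 and lower in 1 (0 held), fatty acid synthesis as lower in 1 (0 held) and aryl hydrocarbon receptor response as lower in 2 (0 held). PPAR and lipid storage passed as higher in 6, of which 5 held. Unfolded protein and retinoic acid response passed in 0, with lowest adjusted p of 0.0926 and 0.115. Among markers of other cells, the lists for B cells, T and NK cells, mast cells and basophils, and stroma and endothelium passed in 0. Neutrophil markers passed in 1, mouse against human serum without LPS, and dendritic cell markers in the 5 comparisons of LPS with none, with 0 held.

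Markers of erythroid cells and megakaryocytes passed as higher in 4 comparisons, all without LPS, namely mouse serum against no serum, calf serum and human serum and the average of the sera against no serum. All but mouse against human serum held with an estimated correlation. They rest on few genes, as 4 of the list were tested. Ppbp, a platelet chemokine gene, rose by 2.27 ± 0.21 in mouse serum without LPS, from 5.26 to 7.53, while Pf4, another platelet chemokine gene that macrophages also express, stood at 12.38 in no serum and 12.67 in mouse serum. With LPS Ppbp had a level of 5.61 in mouse serum and 5.08 in no serum.

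The rise of Cxcl3, Thbs1, Nr4a1, Dusp5 and others in mouse and human serum without LPS was weighed against both contaminants of serum. Endotoxin in the sera could raise Cxcl3, and should then raise the 200 genes with the largest LPS rise in calf serum (median 3.92). Their median was -0.133 (SE 0.0761) in mouse serum, with 27 higher and 32 lower. In human serum it was -0.00781 (SE 0.0616), with 38 higher and 17 lower. Over all 11785 genes 527 were higher and 629 lower in mouse serum, and 557 and 670 in human serum. Calls in both directions were thus more frequent among the 200, most so the higher ones in human serum. A trace of endotoxin is not excluded. RNA carried in with mouse serum may add to the signal, in equal amount with and without LPS, but 29.1% (43 of 148 genes, 95% interval 21.9 to 37.1) had a level with LPS in mouse serum below that amount. Thbs1, Nr4a1, Dusp5 and Ppbp are among these and Cxcl3 is not. For genes below that amount, carried RNA does not make up the whole rise, provided that unlogged values add equally on both sets of arrays. A part of the rise stays open to carried RNA in these genes, and all of it in the others. A response of the cells to serum was not tested apart.

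The excess of lower over higher genes with LPS was weighed against the scaling of the arrays. A shift of the LPS arrays by the same amount at all levels would move the hybridisation controls too, which are added in equal amounts. The median LPS change of these 18 probe sets, averaged over the media, was 0.0438 (SE 0.0118 over the 4 media), on the other side of 0 from the genes. Their mean level was 12.2, while the deposited arrays had medians of 5.04 to 5.13. The controls therefore do not report on a shift lower on the scale. These controls enter after labelling and do not measure the RNA content of a cell. Quantile normalization again left the share of higher genes at 40.4%, in place of 36.4%. The sorted deposited arrays already lay within 0.185 of their mean, so this setting could change little and decides little. With arrays centred the share was 50.4%, but centring itself fixes this balance and decides nothing. How far the excess reflects the cells or the centre of the scale cannot be told apart, because no measure of RNA per cell enters the arrays, and no biological explanation was tested.

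The differences in LPS response were split by where the sera and no serum differed in level. Only level differences in the direction that gives the changed response were counted. Of 320 genes with a larger response in the average of the sera, 89 were lower in the sera without LPS only. Another 183 were higher with LPS only, 19 met both conditions and 29 neither. Of 298 genes with a smaller response, 85 were higher in the sera without LPS only and 169 lower with LPS only. Both conditions were met by 28 and neither by 16. A level call in the other direction does not enter these numbers. Among the arrays, calf serum LPS replicate H stood apart from the other two of its group on the fourth principal component, at 27.4 against 5.91 and 10.6.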
